A study of Mus musculus with 16 samples.

How the data were processed

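RNA sequencing libraries were made from hippocampus and cortex of male mice at postnatal day 47, with a conditional knockout of Foxp1 in forebrain pyramidal neurons or as littermate controls. Per the labels' protocols, the left hemisphere was dissected and frozen, poly(A) RNA was selected, and sequencing was on an Illumina NextSeq. There were 16 samples in 4 groups of 4, each sample placed by its title. Whether a hippocampus and a cortex came from the same mouse is not given in the sources used here, and neither is the deleted part of Foxp1. The design text calls the replicates within a genotype independent.

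The authors deposited a table of CPM (counts-per-million) for 21999 genes in the 16 samples. The submitters' processing notes name STAR (an aligner), HTSeq (a read counter) and edgeR, and the genome builds mm10 and GRCm38, which are 2 names of 1 assembly. Their versions and roles, the annotation, and whether counting used strand are not given in the sources used here. Every column of the deposited CPM table consisted of whole multiples of 1 step, so 100% of the values gave whole reads within a tolerance of 0.001 reads. Each column of the deposited CPM table summed to 1000000, so the values hold no scaling factor beyond the total of the listed genes. The recovered depth ran from 6943136 to 14817870 reads. A single read was worth 0.0675 to 0.144 CPM, so a gene at the expression minimum of 0.5 CPM rests on a handful of reads per library and its counting error is large. Among these genes, 4418 were at 0 in every sample. The 13 mitochondrially encoded genes were all listed at 0, so their list was not tested.

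Per the file headers, the authors also deposited tables of log2 fold changes and adjusted p-values for the genes they called in each region. The adjustment method and the filters are not given in the sources used here. A further table holds q-values of Gene Ontology terms in clusters of genes chosen by the authors, per the file headers. Lists of gene symbols without values give overlaps with autism-associated genes, with genes changed in heterozygous Foxp1 knockouts and with CA1-specific genes. All values called limma, camera or edgeR results were computed here from the CPM table, and the authors' values are named as theirs.

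Within each region, log2(CPM + 0.5) was fitted with limma 3.58.1 (R 4.3.3) by a linear model of genotype with a mean-variance trend, for genes with a mean of at least 0.5 CPM over the 8 samples. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The difference of the genotype effects between regions was an interaction contrast over all 16 samples, with 4 group means and no block. Foxp1 was also tested by a two-sided exact permutation test over the 70 labellings of 8 samples. Because whole reads were recovered, edgeR's quasi-likelihood test (version 4.0.16) was run on them as an alternative. It called 190 genes in hippocampus, 154 of them also called by limma, 1794 in cortex (1647 shared) and 354 for the difference between regions (319 shared).

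Gene lists for cell types, hippocampal subfields, cortical layers, channels, receptors and synaptic functions, 36 in all, were written before the data were examined, as were the tests, the rule for named genes and most of the alternatives. Of these, 35 had at least 3 measured members in each region and were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01. Camera with an estimated correlation and fry, which tests a list on its own, were run beside it. Beside the calls over all genes, each list has the count of members called when p was adjusted over the list alone. Lists overlap, so a gene can count in more than 1.

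The rule for named genes took the FOXP family first. In each region it took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM whose 4 knockout and 4 control values did not overlap, passing over predicted and clone gene models. For the difference between regions it took 5 genes in each direction. From each list it allowed up to 3 members with the smallest p among those passing over the list alone, or up to 2 given as values where none passed. Alternatives were pseudocounts of 0.1 and 1, no expression minimum or 1 CPM, quantile normalization, median-of-ratios rescaling, robust variance estimates, edgeR, an absolute log2 fold change of at least 0.3, all 16 samples in 1 fit, a replicate block, and leaving out each library in turn. Alternatives added after the data were seen were the libraries DJ4 to DJ8 and DJ18 to DJ22 alone, and the myelin or striatal score of each library as a covariate. A score is the mean log2(CPM + 0.5) of a list's members minus the control mean of the region.

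The fits were tested on simulated counts drawn from the real means and depths, with 200 genes changed. In the hippocampal simulation of 13899 genes, 37% of 100 genes changed by a log2 of 0.5 and 81% of 100 genes changed by a log2 of 1 were recovered, and 11 of 129 calls were false. In the cortical simulation of 13713 genes the shares were 54% and 85%, with 6 false calls of 145. For the region difference (13881 genes) they were 22% and 75%, with 3 false calls of 100. The 1 shifted list was called in both regions and none of 30 unshifted lists was. Genes were drawn independently of each other there, so this does not test false calls of lists whose members vary together.

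Symbols were matched to GENCODE release M21 on GRCm38, which holds 21460 of them by the same name. Of 184 named genes, 182 had 1 position, and Ctgf and Nov had none under those symbols. No per-sample column of the table was left out. Values of some members of the lists are not reported here, although counts over the lists include them.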

Results

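The transcriptomes of 2 forebrain regions, hippocampus and cortex, were measured in male mice lacking Foxp1 in forebrain pyramidal neurons and in littermate controls at postnatal day 47. Foxp1 encodes a forkhead transcription factor, and the conditional knockout (cKO) removes it from selected cells rather than from the whole animal. Poly(A) RNA from the left hemisphere gave 16 libraries in 4 groups of 4: control and knockout hippocampus, and control and knockout cortex. The study's design text describes the replicates within a genotype as independent. Libraries are named here by genotype and the DJ number of their titles. Depth was 9578904 to 14817870 reads in control hippocampus, 6943136 to 14055344 in knockout hippocampus, 7075560 to 9037821 in control cortex and 8160441 to 9164571 in knockout cortex. A single read was therefore worth between 0.0675 and 0.144 counts-per-million (CPM). Over the 24 pairs of replicates within groups, the chi-square per degree of freedom of the read counts ran from 2.19 to 17.9, so no pair was as close as counting noise alone would leave it. Changes are given as log2 fold changes, knockout minus control, of log2(CPM + 0.5) with their standard errors (SE). This scale understates the change of genes with few reads.

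Foxp1 was lower in every knockout library than in any control library of the same region. In hippocampus its level was 227 ± 45.3 CPM in controls and 119 ± 16.0 CPM in knockouts (SD, n = 4 each), which is 52.3% of the control level. In cortex it was 284 ± 14.1 CPM in controls and 113 ± 21.2 CPM in knockouts (SD, n = 4 each), or 39.9%. The hippocampal controls DJ17, DJ20, DJ21 and DJ22 held 276, 248, 214 and 171 CPM, and the knockouts DJ15, DJ16, DJ18 and DJ19 held 113, 102, 140 and 121 CPM. The cortical controls DJ3, DJ6, DJ7 and DJ8 held 265, 298, 288 and 286 CPM, and the knockouts DJ1, DJ2, DJ4 and DJ5 held 96.0, 108, 105 and 144 CPM. A two-sided exact permutation test gave p = 0.0286 in each region, the smallest value that 4 against 4 samples allow (2 of 70 labellings). Without knockout DJ15 or knockout DJ16 the exact p in hippocampus was 0.0571. With limma and Benjamini-Hochberg adjustment over all genes, the log2 fold change was -0.92 (SE 0.14, adjusted p = 0.0072) in hippocampus and -1.34 (SE 0.09, adjusted p = 3.9e-08) in cortex. The region difference of 0.42 (SE 0.18) did not pass with limma (adjusted p = 0.30).

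Among the other FOXP genes, Foxp2 rose in cortex, from 43.5 ± 4.91 to 56.6 ± 7.50 CPM (SD, n = 4; log2 fold change 0.37, SE 0.10, limma adjusted p = 0.014). Without control DJ8 that adjusted p was 0.061 with limma. In a fit of all 16 libraries, which pools the spread of both regions, it was 0.47. In hippocampus Foxp2 had a log2 fold change of 0.83 with an SE of 0.35 and did not pass (limma adjusted p = 0.32). The authors' deposited table for hippocampus does list Foxp2 as higher (log2 fold change 0.62, the authors' adjusted p = 7.2e-05). Their table for cortex does not list Foxp2. Foxp4 did not pass in either region over all genes tested, at 0.27 (SE 0.15, limma adjusted p = 0.48) in hippocampus and 0.39 (SE 0.14, limma adjusted p = 0.075) in cortex, where leaving out knockout DJ5 gave 0.022 with limma. Foxp3 was below the expression minimum. Over the 3 measured family members of the fixed list, 1 fell and 2 did not pass in hippocampus, and 1 rose and 1 fell in cortex. Adjusted over the list alone, 2 rose and 1 fell in cortex, Foxp4 being the addition, and the count in hippocampus was 1. As a set the family did not shift with limma's camera test (adjusted p = 0.50 in hippocampus and 0.79 in cortex). The test pointed lower in both regions, against a median of 0.27 and mean of 0.06 in hippocampus and a median of 0.37 and mean of -0.19 in cortex.

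**Figure D1:**
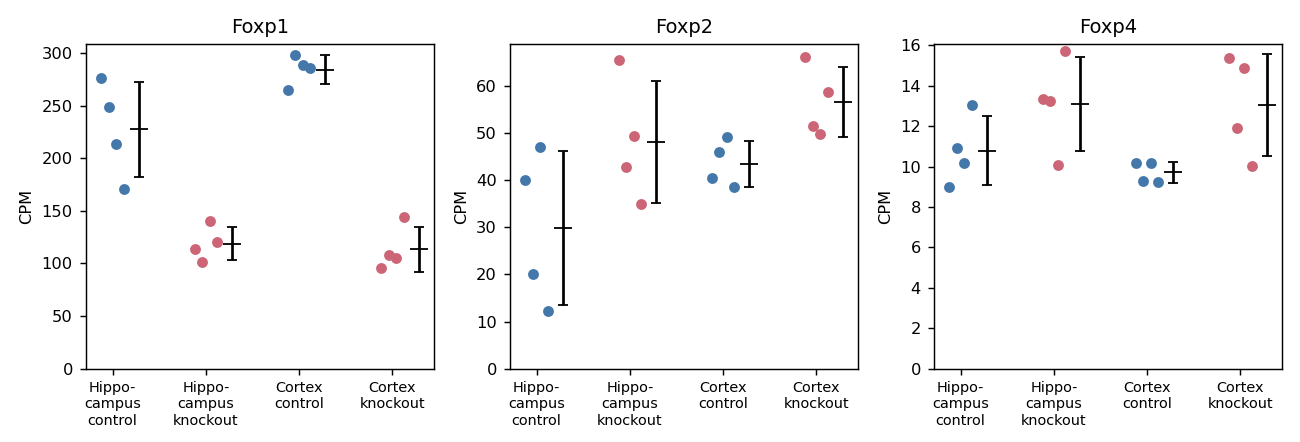
CPM of Foxp1, Foxp2 and Foxp4 in each of the 16 libraries (points), with the mean and SD of each group of 4 beside them (bars), for control and knockout hippocampus and cortex. The Foxp1 points of the knockouts lie between 96.0 and 144 CPM, below those of the controls, which lie between 171 and 298 CPM.

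The hippocampal comparison asks which transcripts differ when Foxp1 is lost from pyramidal neurons of a structure needed for spatial learning. Among the sharpest falls were those of Slc9a4 and Slc9a2, which encode plasma membrane sodium/proton exchangers. Slc9a4 went from 28.4 ± 6.20 to 5.04 ± 1.57 CPM (SD, n = 4; log2 fold change -2.40, SE 0.23) and Slc9a2 from 38.1 ± 6.86 to 10.7 ± 1.88 CPM (log2 fold change -1.78, SE 0.15). Homer2, a postsynaptic scaffold of group I metabotropic glutamate receptors, fell by 1.24 (SE 0.09), from 213 ± 18.3 to 90.0 ± 11.5 CPM. Lipoprotein lipase (Lpl) fell by 1.30 (SE 0.09), and the heparan sulfate sulfotransferase gene Ndst4 by 1.44 (SE 0.14). In the other direction the calcium-binding protein calretinin (Calb2) rose from 10.3 ± 6.13 to 60.5 ± 12.5 CPM (SD, n = 4; log2 fold change 2.64, SE 0.31).

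Further hippocampal genes with large changes included a polycystin-family cation channel, Pkd2l1, which rose from 0.663 ± 0.361 to 8.13 ± 3.22 CPM (SD, n = 4; log2 fold change 2.87, SE 0.29). The fatty acid receptor Cd36 rose by 2.39 (SE 0.16), the alpha-2A adrenergic receptor Adra2a by 1.34 (SE 0.19), the hyaluronan receptor Cd44 by 1.41 (SE 0.22) and the BTB-kelch gene Klhl14 by 1.5 (SE 0.22). Fibin (1.5), Smtn (1.48), Doc2a (1.41) and the protease gene Bace2 (1.36) completed the 10 largest rises under the rule for named genes. The other large falls were Stac (-1.76), Pirt (-1.58), the POU-domain transcription factor Pou3f1 (-1.36), Spink8 (-1.27) and the Ras-related Rasd1 (-1.26). The 20 genes had limma adjusted p between 5.9e-05 (Cd36) and 0.046 (Doc2a). Cd44, Fibin, Rasd1, Smtn, Bace2, Spink8 and Doc2a each missed the threshold when 1 library was left out: Cd44 without knockout DJ16 (adjusted p = 0.051 with limma), Fibin without control DJ20 or knockouts DJ16 or DJ19 (up to 0.073), and Rasd1 without controls DJ20 or DJ21 or knockout DJ16 (up to 0.11). Smtn missed it without controls DJ20, DJ21 or DJ22 or knockouts DJ15 or DJ19 (up to 0.079 with limma). Bace2 missed it without controls DJ20 or DJ21 or knockouts DJ16 or DJ19 (up to 0.11), Spink8 without controls DJ20 or DJ21 or knockouts DJ15 or DJ16 (up to 0.11), and Doc2a without control DJ20 or knockouts DJ15, DJ16 or DJ19 (up to 0.17). The other 13 kept their call with each library left out in turn. Doc2a did not pass by edgeR on the recovered reads (adjusted p = 0.062), with a pseudocount of 0.1 (0.0502) or with quantile normalization (0.060), and Smtn did not pass with quantile normalization (0.055). Among DJ18 to DJ22, a subset chosen after the data were seen, 16 of 48 called genes named for hippocampus, list members included, lost their call. Doc2a (limma adjusted p = 0.16) and Bace2 (0.12) were among them.

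Of 13899 genes tested in hippocampus, 192 passed a limma adjusted p of 0.05 with Benjamini-Hochberg adjustment, 92 higher and 100 lower in knockouts, and 1886 had an unadjusted p below 0.05. A log2 fold change beyond 1 in either direction was seen in 38 of the 192. The split between rises and falls depended on scaling: median-of-ratios rescaling gave 60 rises and 135 falls among 195 genes, quantile normalization 56 and 109 among 165, and edgeR 59 and 131 among 190. The count was 56 without control DJ20, 63 without knockout DJ16, 82 without knockout DJ19, 91 without control DJ21 and 295 without control DJ17, 446 when all 16 libraries shared 1 fit, and 352 with the libraries' myelin score as a covariate, a fit added after the data were seen.

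Markers of CA1 pyramidal neurons, the main output cells of the hippocampus, were the group that fell most clearly. Of the 10 measured, 4 fell and 6 did not pass over all genes tested; adjusted over the list alone, 6 fell and 1 rose. Ndst4 (-1.44), Pou3f1 (-1.36, SE 0.17) and the mannosidase gene Man1a (-0.60, SE 0.08, from 186 ± 18.5 to 123 ± 9.41 CPM, SD, n = 4, limma adjusted p = 0.0045) were among them. The list's median log2 fold change was -0.65, with a camera adjusted p of 1.2e-08 and adjusted p = 0.053 with an estimated correlation. Of the 8 CA2 markers none rose or fell (camera adjusted p = 0.66, pointing lower against a median of 0.04 and a mean of 0.06), Rgs14 having -0.44 (SE 0.16) and Pcp4 0.45 (SE 0.24). Of the 10 CA3 markers 1 rose and 9 did not pass, yet the list ranked below other genes by camera (median -0.14, adjusted p = 0.037; adjusted p = 0.26 with an estimated correlation). That riser was Coch (1.04, SE 0.22, limma adjusted p = 0.045), which missed the threshold without any 1 of controls DJ20, DJ21 and DJ22 or knockouts DJ15, DJ16 and DJ19 (adjusted p up to 0.16 with limma). The CA3 list missed its own threshold without control DJ20 (0.068), control DJ22 (0.053) or knockout DJ15 (0.23), with quantile normalization (0.084) and among DJ18 to DJ22 alone (0.43), a subset chosen after the data were seen. Coch did not pass with quantile normalization (0.060 with limma).

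Of 15 dentate granule cell markers 1 rose and 1 fell over all genes tested, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.59). Calbindin (Calb1) rose by 0.49 (SE 0.10, limma adjusted p = 0.036) and Lct fell by 1.07 (SE 0.23, limma adjusted p = 0.049). Calb1 lost its call without controls DJ20 or DJ21 or knockouts DJ15, DJ16 or DJ19 (adjusted p up to 0.14), and Lct without controls DJ17, DJ20 or DJ21 or those 3 knockouts (up to 0.18). By edgeR neither passed (0.061 and 0.052), and Lct did not with quantile normalization (0.055) nor Calb1 with median-of-ratios rescaling (0.052). The mean of the dentate list was -0.02 and its median 0.02. No gene of immature neurons and proliferation passed over all genes tested, and 2 of 10 rose adjusted over the list alone, Sox11 (0.30, SE 0.07) and Neurod1 (0.47, SE 0.13), with a camera adjusted p of 0.15. Sox11 passed over all genes without control DJ17 (0.026 with limma) or knockout DJ18 (0.048), and Neurod1 without knockout DJ15 (0.045). Markers of cortical layers ranked higher in knockout hippocampus. For the upper layers, 1 of 14 (Calb1) rose over all genes tested and 5 adjusted over the list alone (median 0.36, camera adjusted p = 0.0026; adjusted p = 0.18 with an estimated correlation). Of 18 deep-layer markers none passed over all genes and 3 rose adjusted over the list alone, Etv1 (0.67, SE 0.15), Ctgf (0.77, SE 0.21) and Tbr1 (0.46, SE 0.14). The deep-layer list had a median of 0.41 and a camera adjusted p of 0.014, with adjusted p = 0.29 with an estimated correlation, 0.068 without knockout DJ18 and 0.057 among DJ18 to DJ22. Etv1 passed over all genes without controls DJ17 or DJ21 or knockout DJ15 (limma adjusted p = 0.046, 0.039 and 0.045), and Ctgf without knockout DJ19 (0.037).

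Lists of postsynaptic, sodium and HCN channel and potassium channel genes ranked lower in knockout hippocampus by camera with the preset correlation, and none of the 3 passed with an estimated one. Of 28 postsynaptic scaffold and plasticity genes 2 fell, Homer2 and the calcium/calmodulin kinase subunit Camk2b (-0.35, SE 0.06, limma adjusted p = 0.016); adjusted over the list alone 6 fell and 1 rose. The list's camera adjusted p was 2.5e-05 (median -0.05), and adjusted p = 0.21 with an estimated correlation. None of 13 sodium and HCN channel genes passed over all genes tested and 4 fell adjusted over the list alone, with Scn1a at -0.28 (SE 0.07; limma adjusted p = 0.047 after median-of-ratios rescaling). This list had a median of -0.14 and a camera adjusted p of 6.0e-04, and adjusted p = 0.090 with an estimated correlation. Among 62 potassium channel genes 2 rose and 5 fell, and 6 rose and 9 fell adjusted over the list alone. Kcnab2 fell by 0.78 (SE 0.10) and Kcnq5, a subunit of the M-current, by 0.52 (SE 0.07), while Kcng3 rose by 1.05 (SE 0.13), with limma adjusted p of 0.0026, 0.0043 and 0.0024. The potassium channel list had a camera adjusted p of 0.0029 (median -0.05), and adjusted p = 0.090 with an estimated correlation. Camk2b missed the threshold without control DJ20 or knockouts DJ16 or DJ19 (adjusted p up to 0.071).

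Both called calcium channel genes, Cacna1e (-0.34, SE 0.06) and Cacna1a (-0.36, SE 0.07), fell among 20 measured, with 2 falls also adjusted over the list alone. That list had a median of -0.02 and a camera adjusted p of 0.011, with adjusted p = 0.26 with an estimated correlation and 0.084 with quantile normalization. Of 15 GABA receptor genes 2 fell, among them the subunit Gabra5 (-0.49, SE 0.09), and 3 fell adjusted over the list alone. The GABA list had a median of -0.06 but a mean of 0.01, and a camera adjusted p of 0.010 in the downward direction. It had adjusted p = 0.26 with an estimated correlation, 0.35 with quantile normalization and 0.053 without control DJ22. Among 29 synaptic adhesion genes 2 fell, Cntnap2 (-0.36, SE 0.07) and Lrrtm1 (-0.38, SE 0.08), and 5 fell adjusted over the list alone. The camera adjusted p was 0.0033 (median -0.02), and adjusted p = 0.26 with an estimated correlation and 0.078 with quantile normalization. No presynaptic gene of 28 passed either way; the list's median was -0.01 and its mean 0.02, while camera ranked it lower (adjusted p = 0.043; adjusted p = 0.70 with an estimated correlation, 0.95 with quantile normalization). It missed the threshold without control DJ20 (0.068), DJ21 (0.16) or DJ22 (0.11), or knockout DJ16 (0.068), DJ18 (0.093) or DJ19 (0.18). Of 48 axon guidance genes 1 rose and 2 fell, and 5 rose and 9 fell adjusted over the list alone. Semaphorin 3E (Sema3e) fell by 1.06 (SE 0.09, limma adjusted p = 1.2e-04), Epha6 fell by 0.65 (SE 0.13) and Sema3d rose by 0.71 (SE 0.14). This list's median was 0.04 and its mean -0.01, and camera ranked it lower (adjusted p = 0.041; adjusted p = 0.18 with an estimated correlation and also with quantile normalization). It missed the threshold without control DJ17 (0.12) or DJ22 (0.059), or knockout DJ15 (0.099) or DJ19 (0.15), and among DJ18 to DJ22 (0.46).

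The calls of Cacna1e, Cacna1a, Gabra5, Cntnap2, Lrrtm1, Epha6 and Sema3d did not hold with every library left out, although their direction did. Their log2 fold changes ran from -0.39 to -0.31 for Cacna1e, -0.42 to -0.33 for Cacna1a, -0.53 to -0.41 for Gabra5, -0.40 to -0.31 for Cntnap2, -0.42 to -0.32 for Lrrtm1, -0.76 to -0.53 for Epha6 and 0.56 to 0.83 for Sema3d. Each missed the limma threshold without control DJ20 or knockout DJ19 (adjusted p up to 0.14), and all but Gabra5 also without control DJ21 or knockout DJ16. Cacna1e, Lrrtm1 and Sema3d missed it without control DJ22 too, and Cacna1a and Epha6 without knockout DJ15. With quantile normalization Cacna1e (adjusted p = 0.058) and Sema3d (0.077) did not pass, nor did Sema3d by edgeR (0.052) or after median-of-ratios rescaling (0.062). Sema3e kept its call with each library left out.

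Glutamate receptor lists did not shift in hippocampus: none of 17 ionotropic genes passed, 2 rose adjusted over the list alone (camera adjusted p = 0.60), and none of 7 metabotropic genes passed either way (0.31). Camera pointed lower for both, with medians of 0.06 and 0.03 and means of 0.04 and 0.04. The median of all genes tested in hippocampus was 0.06. Among 31 monoamine and cholinergic receptor genes 2 rose and 3 fell, and 5 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.17). Adra2a rose, while the muscarinic receptor Chrm3 fell by 0.99 (SE 0.16, limma adjusted p = 0.0093) and the serotonin receptor Htr4 by 0.66 (SE 0.13, limma adjusted p = 0.034). Of 22 cadherins and protocadherins 2 fell, Cdh12 (-0.80, SE 0.09, limma adjusted p = 0.0010) and Cdh8 (-0.39, SE 0.08), with 2 rises and 3 falls adjusted over the list alone (camera adjusted p = 0.11). Among 29 extracellular matrix genes 1 rose and 1 fell, and 4 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.43). The collagen gene Col11a1 fell by 0.90 (SE 0.17, limma adjusted p = 0.025) and Col12a1 rose by 0.82 (SE 0.18, limma adjusted p = 0.049). None of 19 neuropeptide genes passed either way (0.19). Of 20 activity-regulated early genes 1 fell, Nptx2 (-0.62, SE 0.13, limma adjusted p = 0.041), also adjusted over the list alone; the list's median was 0.12 and mean 0.10, while camera ranked it lower without passing (0.28). Chrm3 missed the limma threshold without control DJ20 (adjusted p = 0.051). Htr4 and Cdh8 missed it without any 1 of controls DJ20, DJ21 and DJ22 and knockouts DJ15, DJ16 and DJ19 (adjusted p up to 0.11 and 0.13), and Nptx2 without any 1 of those controls and knockouts DJ16, DJ18 and DJ19 (up to 0.17). Col11a1 missed it without controls DJ20 or DJ21 or knockouts DJ16 or DJ19 (up to 0.10), and Col12a1 without those or control DJ17 or knockout DJ15 (up to 0.17). Col12a1 also missed it by edgeR (0.062), after median-of-ratios rescaling (0.052) and with quantile normalization (0.069).

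Genes that reactive astrocytes switch on ranked higher in knockout hippocampus by camera with the preset correlation. Of 11 measured, 3 rose over all genes tested and 4 adjusted over the list alone. Complement C4b rose from 9.05 ± 0.561 to 17.6 ± 1.92 CPM (SD, n = 4; log2 fold change 0.92, SE 0.11, limma adjusted p = 0.0026), beside Cd44 and the oncostatin M receptor Osmr (0.58, SE 0.12, limma adjusted p = 0.042). The list's median was 0.25 and its camera adjusted p 0.0056, with adjusted p = 0.21 with an estimated correlation, and 0.065 without knockout DJ18. Osmr missed the threshold without controls DJ20 or DJ21 or any 1 of the 4 knockouts (adjusted p up to 0.16), by edgeR (0.059), after median-of-ratios rescaling (0.055) and with quantile normalization (0.092). Of 14 general astrocyte markers 1 rose, Sox9 (0.40, SE 0.09, limma adjusted p = 0.046, up to 0.16 without 1 library, control DJ17 excepted), and 2 rose adjusted over the list alone (camera adjusted p = 0.12). Sox9 did not pass by edgeR (0.10), after median-of-ratios rescaling (0.10) or with quantile normalization (0.086).

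Markers of other cell types and neighbouring tissues were measured beside these groups. No member passed in hippocampus for myelin and oligodendrocytes (15 genes, camera adjusted p = 0.64), oligodendrocyte precursors (9 genes, 0.38), microglia (14 genes, 0.57), endothelium and pericytes (14 genes, 0.24), choroid plexus (12 genes, 0.12), meningeal fibroblasts (12 genes, 0.31) or blood (3 genes, 0.31), and none passed adjusted over the list alone. The microglia list had a median of 0.01, below the 0.06 of all genes tested, and camera pointed lower. Calb2, which also belongs to the interneuron and thalamic lists, was the 1 called member among 22 interneuron markers (camera adjusted p = 0.31) and among 9 thalamic markers (0.31); the thalamic list also had a fall of Ntng1 adjusted over the list alone, a median of -0.08 and a mean of 0.10. Over all genes Ntng1 passed by edgeR (adjusted p = 0.046), after median-of-ratios rescaling (0.045) and without knockout DJ18 (0.028). Striatal projection neuron markers ranked higher in knockout hippocampus although none of 12 passed singly (median 0.57, camera adjusted p = 0.038; adjusted p = 0.71 with an estimated correlation). That call was lost without control DJ22 (0.66), knockout DJ15 (0.19) or knockout DJ18 (0.18). The mean striatal score of single libraries, relative to the control mean, ran from -1.39 (DJ22) to 1.08 (DJ17) within the controls. Of the 35 lists tested, 14 were called in hippocampus, 4 higher and 10 lower, none with an estimated correlation. There were 9 with quantile normalization, 5 higher and 4 lower, and 9 without control DJ22, 3 higher and 6 lower. The self-contained test fry called 1, the CA1 list (adjusted p = 0.015).

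In cortex the comparison asks the same question of the neocortical pyramidal neurons and their surroundings. Glra3, a glycine receptor subunit, rose from 30.5 ± 3.94 to 155 ± 5.92 CPM (SD, n = 4; log2 fold change 2.34, SE 0.08). Pkd2l1 rose here too, from 0.133 ± 0.115 to 5.11 ± 2.23 CPM (log2 fold change 3.08, SE 0.28), and the estrogen receptor gene Esr1 from 3.53 ± 0.634 to 16.1 ± 1.87 CPM (log2 fold change 2.05, SE 0.15). Deptor, an inhibitor of mTOR kinase, fell from 79.9 ± 5.06 to 25.1 ± 0.749 CPM (SD, n = 4; log2 fold change -1.65, SE 0.07). The potassium channel beta subunit Kcnab3 fell from 53.2 ± 7.51 to 17.5 ± 0.751 CPM (log2 fold change -1.57, SE 0.10).

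The other large cortical rises were Qrfpr (1.86), Cdhr1 (1.80), gastrin-releasing peptide (Grp, 1.77), Adgrg2 (1.75), the organic cation transporter Slc22a3 (1.73), Alox12b (1.69) and the GLP-2 receptor Glp2r (1.66). The other large falls were the olfactory receptor Olfr78 (-2.24, from 7.71 ± 0.989 to 1.29 ± 0.511 CPM, SD, n = 4), the myosin light chain Myl4 (-1.92), Hsbp1l1 (-1.84), the relaxin family receptor Rxfp2 (-1.66), the potassium channel subunit Kcng4 (-1.55), Prr16 (-1.51), Ky (-1.47) and Vgll3 (-1.44). Their limma adjusted p ran from 6.6e-12 (Glra3) to 8.5e-04 (Kcng4), and each of the 20 kept its call with any 1 library left out, Vgll3 losing its own in a fit of all 16 libraries (0.078). Of 13713 genes tested, 1847 passed a limma adjusted p of 0.05 with Benjamini-Hochberg adjustment, 1047 higher and 800 lower in knockouts, and 3526 had an unadjusted p below 0.05. Of the 1847, 116 had a log2 fold change beyond 1. Median-of-ratios rescaling gave 829 rises and 951 falls among 1780 genes, quantile normalization 886 and 921 among 1807, and edgeR 853 and 941 among 1794. The count was 231 with the libraries' myelin score as a covariate and 937 with their striatal score, both fits added after the data were seen.

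Myelin genes fell together in knockout cortex. Of 15 measured, 13 fell and 2 did not pass, and 13 fell adjusted over the list alone. Myelin basic protein (Mbp) went down by 0.77 on the log2 scale (SE 0.08, limma adjusted p = 2.9e-06), Mobp by 0.85 (SE 0.10, 9.4e-06) and Ermn from 128 ± 14.6 to 74.5 ± 11.4 CPM (SD, n = 4; -0.78, SE 0.09). The list had a median of -0.65 and a camera adjusted p of 1.4e-15, and adjusted p = 0.18 with an estimated correlation. Of 9 oligodendrocyte precursor markers 1 rose, Pdgfra (0.26, SE 0.06), and 1 fell, Olig1 (-0.43, SE 0.10), the same adjusted over the list alone (camera adjusted p = 0.40). Astrocyte markers were lower: 5 of 14 fell and 1 rose, and 6 fell and 2 rose adjusted over the list alone. S100b fell by 0.39 (SE 0.07), the connexin Gjb6 by 0.59 (SE 0.11) and Fgfr3 by 0.39 (SE 0.08). Their list had a median of -0.14 and a camera adjusted p of 0.0057, and adjusted p = 0.30 with an estimated correlation. In a fit of all 16 libraries Gjb6 did not pass (limma adjusted p = 0.053). None of 9 reactive astrocyte genes passed either way (0.95).

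Vascular genes of endothelium and pericytes ranked lower, with 2 of 14 falling, Rgs5 (-0.30, SE 0.08) and Ly6c1 (-0.50, SE 0.15), and 2 adjusted over the list alone. The camera adjusted p was 0.037, with adjusted p = 0.55 with an estimated correlation, and 0.25, 0.13 and 0.13 without control DJ3, knockout DJ4 and knockout DJ5. Ly6c1 missed the threshold without controls DJ6, DJ7 or DJ8 or knockout DJ2 (limma adjusted p up to 0.10), or in a fit of all 16 libraries (0.10). No gene passed, over all genes or adjusted over the list alone, among 14 microglial (camera adjusted p = 0.21), 7 choroid plexus (0.89), 12 meningeal fibroblast (0.70) and 4 blood genes (0.61). Of 9 thalamic markers 2 rose and 2 fell, also adjusted over the list alone; the median was 0.01 and the mean 0.08, with camera pointing lower (0.89). The vesicular glutamate transporter Slc17a6 was among the rises and the nuclear receptor gene Rora among the falls, and neither passed in a fit of all 16 libraries (limma adjusted p = 0.28 and 0.19). Rora also missed the threshold without controls DJ6, DJ7 or DJ8 or knockout DJ4 (up to 0.089).

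Markers of striatal projection neurons rose in knockout cortex, 8 of 12 over all genes tested and 11 adjusted over the list alone. Proenkephalin (Penk) rose from 50.4 ± 14.9 to 105 ± 25.0 CPM (SD, n = 4; log2 fold change 1.07, SE 0.17, limma adjusted p = 3.1e-04). The list's median was 0.80 and its camera adjusted p 1.1e-05, with adjusted p = 0.37 with an estimated correlation. In a fit of all 16 libraries Penk did not pass by limma (adjusted p = 0.066). The libraries differed within the genotypes too: the mean score of the list, relative to the control mean, was -0.64 and -0.33 in controls DJ3 and DJ8 and 0.47 and 0.49 in controls DJ6 and DJ7. Neuropeptide genes were higher, with 8 of 19 rising over all genes tested, and 11 rising and 1 falling adjusted over the list alone. Besides Penk, which is in both lists, these included Grp and substance P precursor Tac1 (0.61, SE 0.13, limma adjusted p = 0.0035). Their median was 0.40 and their camera adjusted p 0.0018, and adjusted p = 0.30 with an estimated correlation. Activity-regulated early genes also ranked higher: 5 of 20 rose, 7 adjusted over the list alone, among them Bdnf (0.54, SE 0.08, limma adjusted p = 1.4e-04) and Egr2 (1.74, SE 0.34, limma adjusted p = 0.0016). The activity list had a median of 0.33 and a camera adjusted p of 0.0057, with adjusted p = 0.60 with an estimated correlation, and 0.11 without knockout DJ1. Its score, relative to the control mean, was 0.47 in control DJ3, 0.92 in knockout DJ1 and 0.50 in knockout DJ2, and between -0.27 and 0.17 in the libraries DJ4 to DJ8.

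Layer and subfield markers moved in knockout cortex in ways that differed within a list. Among 14 upper-layer markers 8 rose and 2 fell, and 10 rose and 2 fell adjusted over the list alone. Calb1 rose by 0.89 (SE 0.06) and Lamp5 by 0.54 (SE 0.05), whereas Rorb, a nuclear receptor of layer 4 neurons, fell by 0.93 (SE 0.07), from 238 ± 22.8 to 125 ± 8.54 CPM (SD, n = 4, limma adjusted p = 6.7e-08). The list had a median of 0.34 and a camera adjusted p of 0.0021, with adjusted p = 0.18 with an estimated correlation. The 18 deep-layer markers split evenly, 5 up and 5 down, or 6 and 5 adjusted over the list alone, with Deptor and Sulf2 (-0.88, SE 0.07) down and Nr4a2 (1.22, SE 0.13) up (camera adjusted p = 0.92). Genes that mark CA1 in hippocampus were higher in knockout cortex, 3 of 9 rising and 1 falling, the same adjusted over the list alone. Wfs1 rose by 1.17 (SE 0.08) and Nov by 1.31 (SE 0.09), and Pou3f1 fell by 0.75 (SE 0.12). The CA1 list had a median of 0.25 and a camera adjusted p of 0.0057, and adjusted p = 0.18 with an estimated correlation.

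CA2 markers rose in 5 of 8 cases and fell in 1 (6 and 1 adjusted over the list alone), led by Necab2 (0.98, SE 0.15) and Rgs14 (0.80, SE 0.14). Their camera adjusted p was 0.0057 (median 0.57), and adjusted p = 0.18 with an estimated correlation and 0.066 among DJ4 to DJ8, a subset chosen after the data were seen. Dentate markers rose in 5 of 13 cases and fell in 1 (7 and 1 adjusted over the list alone), with Stxbp6 up by 0.55 (SE 0.06) and Npnt down by 0.94 on the log2 scale (SE 0.09). Their camera adjusted p was 0.020 (median 0.29), and adjusted p = 0.18 with an estimated correlation. Of 9 CA3 markers 1 rose and 3 fell, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.61). Nectin3 rose and Bok and Elavl2 fell among them, Bok missing the limma threshold without controls DJ3 or DJ6 or knockout DJ5 (adjusted p up to 0.059). Genes of immature neurons rose in 3 of 7 cases, also adjusted over the list alone: Sox11 by 0.70 (SE 0.08), Neurod1 by 0.47 (SE 0.08) and Sox4 by 0.40 (SE 0.09). This list had a camera adjusted p of 0.0057 (median 0.38), and adjusted p = 0.18 with an estimated correlation and 0.079 among DJ4 to DJ8. Interneuron markers went both ways, 5 of 22 up and 2 down, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.39). Parvalbumin (Pvalb), of fast-spiking interneurons, fell from 42.3 ± 1.73 to 19.5 ± 1.83 CPM (SD, n = 4; -1.10, SE 0.09, limma adjusted p = 1.6e-07), while Nos1 rose by 0.93 (SE 0.08) and Reln by 0.56 (SE 0.06).

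Ion channel genes of the cortex changed in many members. Of 61 potassium channel genes 16 fell and 9 rose, and 22 fell and 12 rose adjusted over the list alone. Besides Kcnab3, the inward rectifier Kcnj10, which astrocytes carry, fell by 0.85 (SE 0.07). The list had a median of -0.16 and a camera adjusted p of 0.0018, with adjusted p = 0.18 with an estimated correlation. Of 13 sodium and HCN channel genes 6 fell and 3 rose (7 and 3 adjusted over the list alone), with Scn1a down by 0.91 on the log2 scale (SE 0.06) and Scn3b up by 0.76 (SE 0.07) (camera adjusted p = 0.095). Calcium channel genes rose in 6 and fell in 5 of 20 cases (8 and 5 adjusted over the list alone), Cacnb4 having -0.41 (SE 0.06) and Cacna2d1 0.29 (SE 0.05) (camera adjusted p = 0.80).

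Synaptic adhesion genes rose in knockout cortex, 10 of 29 with no falls, and 10 adjusted over the list alone. Lrrtm4 went from 51.0 ± 3.32 to 92.5 ± 8.66 CPM (SD, n = 4; log2 fold change 0.85, SE 0.08, limma adjusted p = 5.6e-07), Cntn6 rose by 0.80 (SE 0.07) and Cadm3 by 0.35 (SE 0.05). Their list had a median of 0.13 and a camera adjusted p of 2.2e-04, with adjusted p = 0.18 with an estimated correlation. Of 28 presynaptic genes 8 fell and 2 rose (8 and 3 adjusted over the list alone), including Vamp1 (-0.90, SE 0.06), Cplx1 (-0.55, SE 0.05) and Snap25 (-0.41, SE 0.04). That list's median was 0.01 and its mean -0.10, and camera ranked it lower (adjusted p = 0.0057; adjusted p = 0.18 with an estimated correlation and 0.19 with quantile normalization, where Snap25 did not pass). Postsynaptic scaffold genes rose in 4 and fell in 4 of 28 cases (5 and 4 adjusted over the list alone; camera adjusted p = 0.26), Camk4 having -0.49 (SE 0.06).

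Among receptors, 5 of 17 ionotropic glutamate genes rose and none fell (6 adjusted over the list alone), including Grin3a (0.57, SE 0.07) and Gria3 (0.35, SE 0.05), though the list did not pass as a set (camera adjusted p = 0.096). Of 7 metabotropic glutamate genes 2 rose and 2 fell (3 and 3 adjusted over the list alone), Grm5 having 0.40 (SE 0.05) and Grm2 -1.30 (SE 0.17), with a list median of 0.15, a mean of -0.13 and a camera adjusted p of 0.89. GABA receptor genes rose in 3 and fell in 3 of 15 cases (6 and 3 adjusted over the list alone), with Gabra5 at -0.74 (SE 0.06) and Gabra2 at 0.46 (SE 0.05) (0.74). Monoamine and cholinergic receptor genes rose in 8 and fell in 7 of 29 cases (9 and 9 adjusted over the list alone), Htr2c having 1.20 (SE 0.13) and Adra1b -0.95 (SE 0.15); median and mean were 0.04 and 0.06 while camera pointed lower (0.89). Axon guidance genes rose in 9 and fell in 7 of 48 cases (11 and 9 adjusted over the list alone), Sema3a having 0.89 (SE 0.07) and Sema7a -0.75 (SE 0.08) (0.74). Cadherins and protocadherins rose in 8 and fell in 4 of 22 cases (10 and 5 adjusted over the list alone), Pcdh8 having 1.22 (SE 0.11) and Pcdh7 -0.57 (SE 0.05) (0.19). Extracellular matrix genes rose in 7 and fell in 3 of 29 cases (8 and 6 adjusted over the list alone), Col5a1 having 1.03 (SE 0.10) and Hapln4 -0.84 (SE 0.07); their median of 0.02 and mean of 0.05 had the opposite sign to camera (0.80). Of the 35 lists, 14 were called in cortex, 9 higher and 5 lower, and none with an estimated correlation.

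**Figure D2:**
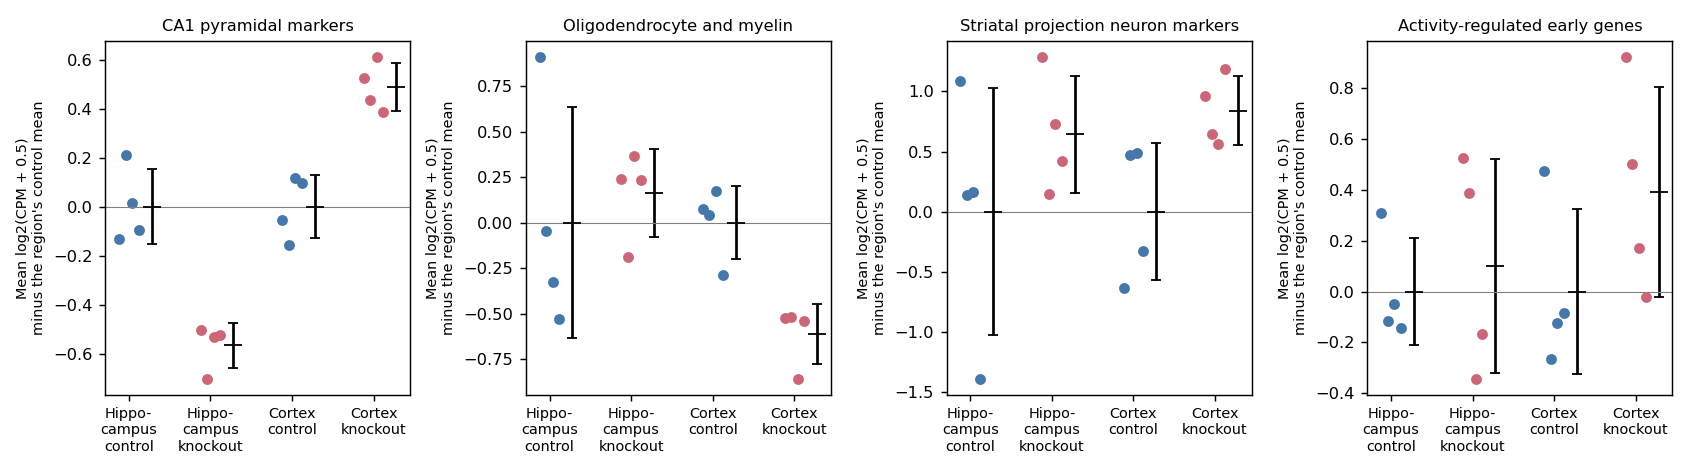
Mean log2(CPM + 0.5) over the members of 4 fixed lists in each of the 16 libraries (points), relative to the control mean of the same region, with the mean and SD of each group of 4 beside the points. The CA1 scores of the knockout hippocampi lie between -0.70 and -0.51 and those of the knockout cortices between 0.39 and 0.61, while the striatal scores of the control hippocampi span -1.39 to 1.08.

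The design also allows the genotype effects of the regions to be compared with each other. Several genes changed in opposite directions. Lpl fell in hippocampus (-1.30, from 120 ± 13.9 to 48.4 ± 4.92 CPM, SD, n = 4) and rose in cortex (1.60, SE 0.11), from a control mean of 32.2 to a knockout mean of 99.0 CPM, a difference of -2.90 (SE 0.16, limma adjusted p = 9.8e-10). Ndst4 did the same (-1.44 and 1.54), with a difference of -2.98 (SE 0.48, limma adjusted p = 0.0012). The heparanase gene Hpse rose in hippocampus (1.26) and fell in cortex (-0.84), a difference of 2.10 (SE 0.35, limma adjusted p = 0.0014). Its mean in control hippocampus was 0.355 CPM. Slc9a4 and Slc9a2, which fell in hippocampus, were at 0.496 and 2.88 CPM in control cortex and did not pass there (0.46 and 0.38, limma adjusted p = 0.29 and 0.38); their differences were -2.86 (SE 0.32, limma adjusted p = 3.0e-05) and -2.16 (SE 0.32, limma adjusted p = 4.4e-04).

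Stac, which fell in hippocampus and had a cortical log2 fold change of 0.62 that did not pass, had a difference of -2.38 (SE 0.40, limma adjusted p = 0.0015). Its cortical means were 0.357 CPM in controls and 0.905 CPM in knockouts. Olfr78 and Myl4 fell in cortex and had differences of 2.19 (SE 0.32) and 2.18 (SE 0.32), with hippocampal log2 fold changes of -0.05 and 0.26. In control and knockout hippocampus, Olfr78 had means of 0.560 and 0.528 CPM and Myl4 of 0.945 and 1.29 CPM. A fall from such levels could hardly be seen. Bace2 differed by 2.06 (SE 0.40, limma adjusted p = 0.0063). The largest difference was in Vgll3, at 3.92 (SE 0.72, limma adjusted p = 0.0042). Its hippocampal value of 2.48 did not pass, and control hippocampi held 1.70 to 25.2 CPM and knockout hippocampi 18.4 to 50.7 CPM. Of 13881 genes, 378 passed the interaction test by limma with Benjamini-Hochberg adjustment, 163 with a more positive effect in hippocampus and 215 with a more positive effect in cortex; 1915 had an unadjusted p below 0.05 and edgeR called 354. The count was 248 without hippocampal control DJ20, 699 without hippocampal control DJ17 (372 and 327 in the same order) and 772 (386 and 386) among the libraries numbered DJ4 to DJ8 and DJ18 to DJ22, a subset chosen after the data were seen.

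For gene lists, the difference between regions was clearest for CA1 markers, with medians of -0.65 in hippocampus and 0.21 in cortex over the 10 genes tested in the joint fit (median of the differences -0.79, camera adjusted p = 1.2e-09). Synaptic adhesion genes differed likewise (median difference -0.25, camera adjusted p = 8.0e-09). These calls held with an estimated correlation, at adjusted p = 0.0032 and 0.033. Myelin genes differed in the other direction (0.77, camera adjusted p = 4.0e-08, and adjusted p = 0.29 with an estimated correlation). Postsynaptic scaffold genes (-0.14), CA2 markers (-0.56), dentate markers (-0.39), cadherins (-0.21) and activity-regulated genes (-0.21) had lower effects in hippocampus, and deep-layer (0.38), astrocyte (0.21), reactive astrocyte (0.30) and endothelial genes (0.31) higher ones, as medians of the differences. Altogether 12 of 35 lists were called for a difference by camera with the preset correlation. The 10 of them other than CA1 and synaptic adhesion did not pass with an estimated correlation (adjusted p = 0.096 to 0.44 with an estimated correlation).

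Calls shared by the regions were compared with the number that independent calls would share. Pkd2l1, Cd36 and Calb2 rose in both regions (cortical log2 fold changes 3.08, 1.06 and 0.71), as did Hrk, a pro-apoptotic BCL2-family gene (1.23 in hippocampus and 0.69 in cortex). Foxp1, Pou3f1, Gabra5, Kcnab2 and Kcnq5 fell in both. Among 13497 genes tested in both regions, 35 rose in both and 29 fell in both, where n1 × n2 / N gives 6.80 and 5.77. With quantile normalization the counts were 23 and 35, and without hippocampal knockout DJ15 they were 26 and 29. A further 18 were called in opposite directions, where it gives 12.8. Lpl, Ndst4, Sorcs3, Plk2, Ptgs2 and Dgkb were among these 18, each lower in knockout hippocampus and higher in knockout cortex. Hrk, Sorcs3, Plk2, Ptgs2 and Dgkb lie outside the rule for named genes and were chosen after their values were seen. The cortical call of Calb2 (limma adjusted p = 0.039) was lost without any 1 library except knockout DJ5 (up to 0.15). It was also lost in a fit of all 16 libraries (limma adjusted p = 0.13) and among DJ4 to DJ8 (0.48). Of 186 hippocampal calls tested in cortex, 124 had the same sign there (66.7%), and of 1838 cortical calls tested in hippocampus 1327 did (72.2%). Across genes, which are not independent replicates, the log2 fold changes of the regions had a Pearson r of 0.287 and a Spearman rho of 0.262. The shared count was 22 without hippocampal control DJ20, 29 without hippocampal knockout DJ16, 31 without hippocampal knockout DJ19 and 36 without hippocampal control DJ21, and r was 0.104 among the libraries numbered DJ4 to DJ8 and DJ18 to DJ22.

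**Figure D3:**
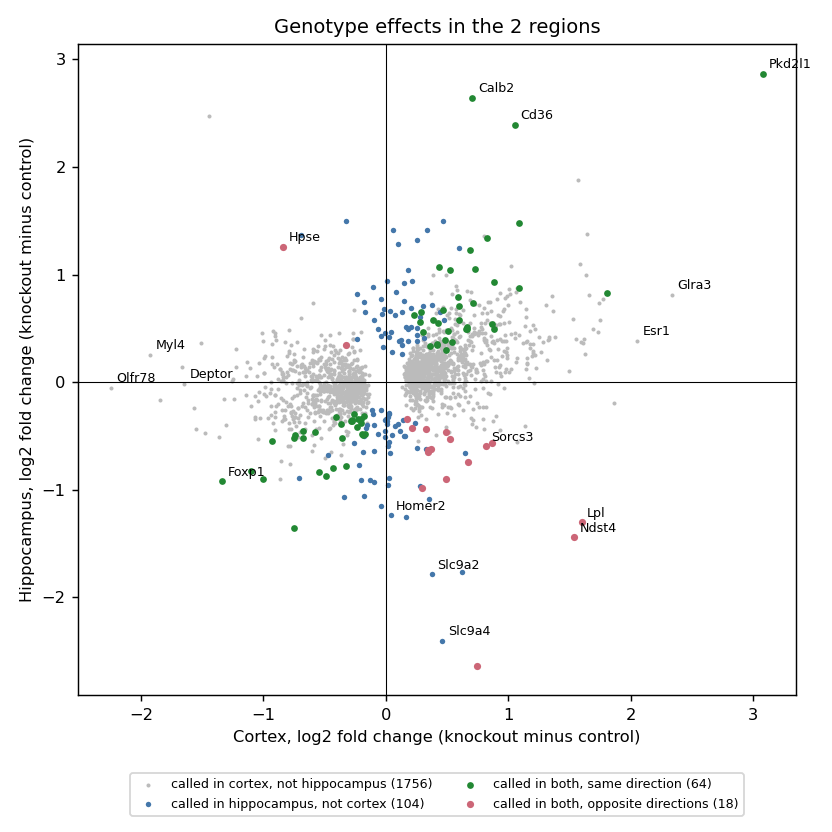
Log2 fold change (knockout minus control) in cortex (horizontal axis) against that in hippocampus (vertical axis) for every gene tested in both regions and called in at least 1. Colours show where a gene was called: 1756 in cortex and not in hippocampus, 104 in hippocampus and not in cortex, 64 in both with the same sign and 18 in both with opposite signs. Pkd2l1 lies at the upper right, Lpl and Ndst4 at the lower right.

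The authors' own results were deposited beside the expression values. The authors' deposited table for hippocampus lists 243 genes, 99 higher and 144 lower, with adjusted p up to 0.0049 and absolute log2 fold changes from 0.317. All 243 had the same sign in the limma fit, and 127 of them (52.3%) were called there, as were 126 by edgeR. The authors' deposited table for cortex lists 874 genes, 418 higher and 456 lower, with adjusted p up to 0.0049 and absolute log2 fold changes from 0.30; all had the same sign in the limma fit and 854 (97.7%) were called. The limma fit called 65 hippocampal and 993 cortical genes that those tables do not list. For Slc9a4 in hippocampus the authors' deposited table gives a log2 fold change of -2.54, and for Glra3 in cortex it gives 2.31. Of the genes that the authors' deposited table marks as listed by SFARI, a database of autism-associated genes, 48 of 48 higher and 36 of 37 lower genes were called in cortex, and 5 of 6 higher and 14 of 18 lower genes in hippocampus. Of the hippocampal genes that the authors' deposited table marks as CA1-specific, 20 of 31 lower and 1 of 5 higher genes were called. The authors chose these subsets from the same libraries, so the counts are not independent evidence of direction.

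Gene positions are given on GRCm38 from GENCODE release M21. Foxp1 lies on chromosome 6 from 98925338 to 99522721 on the minus strand. Slc9a4 (chromosome 1, 40580081 to 40630725) and Slc9a2 (chromosome 1, 40680574 to 40769273) are neighbours on the plus strand. Pkd2l1 lies on chromosome 19 from 44147637 to 44192442, Calb2 on chromosome 8 from 110137502 to 110168210, Lpl on chromosome 8 from 68880491 to 68907448, Glra3 on chromosome 8 from 55940460 to 56130070 and Deptor on chromosome 15 from 55112317 to 55259271. All are protein-coding, and the deposited values count reads over whole genes. The part of Foxp1 that was deleted is not given in the sources used here, and reads from any exons left in place would count towards its level. Of 43 genes named for the size of their change, as FOXP family members or for a region difference, 16 share exon sequence with another annotated gene. They are Adgrg2, Deptor, Doc2a, Foxp1, Glp2r, Homer2, Kcnab3, Klhl14, Myl4, Olfr78, Pou3f1, Rxfp2, Slc22a3, Slc9a4, Smtn and Stac. How the counting treated shared sequence and strand is not given in the sources used here, so the source of some of their reads is uncertain.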

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

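The exact tests of the striatal, myelin and activity scores by genotype, the test of the activity score by library number, the splits matched by library number and the alternatives with a subset of libraries or with a score as a covariate were chosen only after the result was seen.

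Among 254 groups of 4 values examined for a library far from the others, 14 (5.51%) held one, where chance flags about 1 in 20 groups. Control hippocampus DJ22 had 12.5 CPM of Adra2a, against 7.16 to 7.93 in the other controls, and 1.96 CPM of Stac, against 3.03 to 3.20. Control hippocampus DJ17 had 19.1 CPM of Slc9a4, against 31.2 to 31.7. Knockout hippocampus DJ16 had 55.7 CPM of Lpl, against 45.2 to 46.4, and knockout hippocampus DJ15 had 2.36 CPM of Myl4, against 0.783 to 1.01. In cortex, knockout DJ5 had 10.3 CPM of Qrfpr, against 8.66 to 8.85.

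Scores of 8 lists stood apart in the same way. In hippocampus these were the CA1 score of knockout DJ16 (-0.70, others -0.53 to -0.51), the oligodendrocyte precursor score of control DJ17 (0.18, others -0.08 to -0.05), the GABA receptor score of knockout DJ18 (-0.26, others 0.07 to 0.11) and the potassium channel score of knockout DJ15 (0.099, others -0.05 to -0.03). In cortex, knockout DJ1 had a CA2 score of 0.88 (others 0.39 to 0.43) and a neuropeptide score of 0.68 (others 0.35 to 0.37). Knockout cortex DJ4 had a myelin score of -0.86 (others -0.54 to -0.52), and control cortex DJ6 a calcium channel score of 0.064 (all others -0.02).

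The genotype effect differed between the regions by limma's interaction test with Benjamini-Hochberg adjustment for each of the following genes. As hippocampus minus cortex on the log2 scale, the differences were 3.92 for Vgll3, 2.19 for Olfr78, 2.18 for Myl4, 2.10 for Hpse and 2.06 for Bace2. In the other direction they were -2.98 for Ndst4, -2.90 for Lpl, -2.86 for Slc9a4, -2.38 for Stac and -2.16 for Slc9a2. All 10 kept their call with each of the 16 libraries left out in turn and by edgeR. Lpl and Ndst4 fell in hippocampus and rose in cortex, Hpse did the reverse, and for the other 7 the effect passed in 1 region.

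By camera with the preset correlation, 12 lists differed between the regions, of which 2, the CA1 and synaptic adhesion lists, passed with an estimated correlation (adjusted p = 0.0032 and 0.033) and 10 did not. The medians of the differences, hippocampus minus cortex, were -0.79 for CA1 markers, -0.56 for CA2 markers, -0.39 for dentate markers, -0.21 for activity-regulated genes, -0.14 for postsynaptic scaffolds, -0.25 for synaptic adhesion and -0.21 for cadherins. They were 0.38 for deep-layer markers, 0.21 for astrocyte markers, 0.30 for reactive astrocyte genes, 0.77 for myelin and 0.31 for endothelium and pericytes. In 7 of 100 splits of both regions' libraries, the real one included, at least 12 lists were called, and the highest other count was 14, so chance is not excluded for this number of lists.

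Striatal markers were higher in all 4 knockout cortices than in the 4 controls (median log2 fold change 0.80 over 12 members, two-sided exact permutation p of the score 0.0286, the smallest that 4 against 4 allow), Penk going from 50.4 ± 14.9 to 105 ± 25.0 CPM (SD, n = 4). A difference in library scaling is argued against, since the list kept its camera call under quantile normalization and median-of-ratios rescaling (adjusted p up to 4.7e-06), although with an estimated correlation of 0.81 it did not pass (adjusted p = 0.37). When each marker was adjusted for the mean of the other markers within libraries, the median difference went from 0.80 (median SE 0.22) to -0.072 (median SE 0.25), the markers tracked that mean with a median slope of 0.91, and their log2 fold changes spread with a chi-square per degree of freedom of 1.56. This is what striatal tissue carried into some cortical dissections would give, and such carry-over may account for the rise. All 12 genes were above the expression minimum in cortex, but libraries with striatal tissue count towards it, so this does not weigh against carry-over. A genotype effect that moves all these genes together stays open, because the adjustment removes it too.

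Myelin genes were lower in all 4 knockout cortices (median -0.65 over 15 members, two-sided exact permutation p of the score 0.0286). Scaling is argued against here too (camera adjusted p up to 7.4e-14 under both rescalings), although with an estimated correlation of 0.64 the list did not pass (adjusted p = 0.18). With each member adjusted for the others the median went from -0.65 (median SE 0.10) to -0.10 (median SE 0.22). Less white matter in the knockout dissections or a joint effect of genotype on oligodendrocytes would each give this. The changes were unequal (chi-square per degree of freedom 2.87, Aspa at -0.93 and Opalin at 0.05), which either could give. Both may contribute, and the tables do not decide between them.

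Activity-regulated genes had a higher mean score in knockout cortex (0.39), but the scores overlapped (two-sided exact permutation p = 0.171). Among the libraries DJ4 to DJ8 the difference was 0.23, and control DJ3 had 0.47 where the other controls had at most -0.08. In hippocampus the difference was 0.10 over all libraries and -0.15 among DJ18 to DJ22. Collection order or handling that follows the library number may add to the difference. The list kept its camera call among DJ4 to DJ8 (adjusted p = 0.023), and lost it without knockout DJ1 (0.11), by fry (0.22) and with an estimated correlation (0.60). Order or handling cannot be told apart from genotype, because the difference among DJ4 to DJ8 lies between the sizes that each would give and only 2 knockouts and 3 controls of the cortex remain there.

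Other groupings of the same libraries were tested to see how often chance gives results as large, each real split counted as 1. For genes in hippocampus chance is excluded (192 genes, highest of the other splits 2), as it is for genes in cortex (1847, highest other 0). The number of lists called in cortex was also above that of every other split (14, highest other 11). Other splits called lists as well, so this speaks for the total and not for any single list. For lists in hippocampus chance is not excluded: 4 of 35 splits, the real one included, called at least 14, and the highest other count was 15. For the region difference the real split gave 378 genes and the highest of the others 279, over 100 splits. Those splits relabel genotype in both regions, so a genotype effect in 1 region alone could also give this. They test for any genotype effect and not for a difference between the regions. For the correlation of the effects the values were 0.287 and 0.194, so chance is excluded over 100 splits, if the regions are independent. For genes called in both regions the counts were 64 and 0, but other splits of a region called at most 2 genes and so had almost none to share, which makes this no test of the sharing. When the splits of both regions were matched by library number, the highest other count for the region difference was 1, which again tests for any genotype effect only. For the correlation, 5 of 35 matched splits gave a correlation as large as 0.287, and the highest other was 0.348, although the covariance of the effects was larger in the real split (0.0181) than in any other (highest 0.0154). A correlation of this size is therefore not excluded by chance if libraries of the same number, less 14 in hippocampus, share an animal or a day, which is not given in the sources used here.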

How the results depend on the processing

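The fits of the libraries DJ4 to DJ8 and DJ18 to DJ22 and those with a score as covariate were chosen only after the result was seen. No named gene that passed and no called list reversed its direction under the alternatives tried for it. Single genes were not followed with another expression minimum, robust variance estimates, a replicate block or a score as a covariate. Lists were not followed with a score as a covariate, and the adjustment of striatal and myelin markers for one another is not counted here. The balance of rises and falls turned in hippocampus, from 92 and 100 to 230 and 216 when all 16 samples shared 1 fit, 158 and 137 without control DJ17, 81 and 78 without control DJ22, 135 and 118 among DJ18 to DJ22 and 202 and 150 with the myelin score as a covariate. It also turned in cortex, from 1047 and 800 to 829 and 951 with median-of-ratios rescaling, 886 and 921 with quantile normalization and 853 and 941 by edgeR. Under all planned settings other than leaving out a library, the gene counts of each region stayed within 1.5 times the reported ones, except that 446 genes were called in hippocampus when all 16 samples shared 1 fit, which called 1428 in cortex; the cause was not tested. With the myelin score as a covariate 352 genes were called in hippocampus and 231 in cortex, and with the striatal score 937 in cortex. The cause was not tested, although in cortex both scores separate the genotypes and so take up part of the effect. Among DJ4 to DJ8 and DJ18 to DJ22 the region difference had 772 genes, and the correlation of the effects was 0.104 (against 0.287, jackknife SE 0.0935); the cause was not tested.

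Of the 14 lists called in each region, 0 were called with an estimated correlation in hippocampus and 0 in cortex. By fry 1 list was called in hippocampus and 16 in cortex, and camera called 9 in hippocampus after quantile normalization; the cause was not tested.

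With 1 library left out, the lowest and highest values were 56 to 295 genes in hippocampus, 1385 to 1936 in cortex and 248 to 699 for the region difference. They were 9 to 16 lists in hippocampus, 13 to 14 in cortex and 22 to 93 genes called in both regions, with a correlation of 0.225 to 0.312. The log2 fold change of Foxp1 ran from -1.05 to -0.82 in hippocampus and from -1.46 to -1.26 in cortex. Its exact p in hippocampus was 0.0571 without knockout DJ15 (-0.90) or DJ16 (-0.85), and 0.0286 without any other 1 library. Overlaps with the authors' deposited tables were 92 and 830 genes with no expression minimum, against 127 and 854.

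Over the other settings, called named genes kept their call in 701 trials and lost it in 13 in cortex, and kept it in 296 and lost it in 40 in hippocampus. With 1 library left out the counts were 797 and 19 in cortex and 262 and 122 in hippocampus. Named genes that had not passed came to pass in 3 trials in cortex and 31 in hippocampus, or 4 and 22 with 1 library left out. The 10 genes named for the region difference kept theirs in all 60 and 160 trials. Called lists kept theirs in 112 trials and lost it in 56, and with 1 library left out in 201 and 23. With hippocampal numbers less 14 matched to cortical numbers as a replicate block, 520 genes were called for the region difference (fixed block) or 546 (random block, correlation 0.117), against 378. Of the 8 matched pairs, 6 correlated above 0.1 (-0.0132 to 0.210), where the mean correlations with other numbers ran from -0.0489 to 0.00494, and the genotypes match within each pair. None of them correlated best with its own number, so whether the numbers pair the samples stays open. Depth limits genes near 0.5 CPM, and the simulated recovery of a log2 change of 0.5 was 37% in hippocampus and 54% in cortex, so genes that did not pass there can still have changed by that much.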

Other observations

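The comparison with heterozygous knockouts and its splits were set before the result was seen, while the single genes followed across libraries in the last 2 paragraphs were chosen only after their values were seen.

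Genes that the authors' deposited table lists as changed in heterozygous Foxp1 knockouts were compared with the calls made here; their tissue of origin is not given in the sources used here. Of 681 genes listed as lower and tested in hippocampus, 46 fell in the conditional knockout, where independent lists would share 4.90 (Fisher's exact test, odds ratio 17.7, Benjamini-Hochberg adjusted p = 6.3e-33), and 10 rose, where 4.51 would. Of 592 listed as higher, 15 rose (3.92 by independence) and 2 fell (4.26). As sets tested by camera with an estimated correlation, the lower list pointed lower in hippocampus (unadjusted p = 0.0144), and the higher list had an unadjusted p of 0.321. These camera p-values were not adjusted over the lists and regions, so no call is made from them. In cortex every overlap was above the number that independence gives: 127 of 576 genes listed as higher rose (44.0 by independence) and 53 fell (33.6), and of 677 listed as lower 94 fell (39.5) and 125 rose (51.7). Neither list passed there by camera with an estimated correlation (unadjusted p = 0.0954 and 0.731). Genes are not independent, so Fisher's p is too small. Genes shared in the same direction numbered 61 in hippocampus and 221 in cortex, and at most 1 and 0 in the other splits of the libraries (1 of 35 splits, the real one, gave as many in each region). Those splits called at most 2 and 0 genes, so they test the number of calls and not their overlap with the lists.

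The authors' deposited table of Gene Ontology terms holds 6 numbered clusters, with 52, 60, 32, 9, 55 and 13 terms. According to the authors' deposited table, the terms with the lowest q-value in each were neuron projection (1.2e-05), learning or memory (5.3e-04), axon (0.0013), caveola (0.043), intrinsic component of plasma membrane (5.2e-06) and dendrite (0.020). Which genes form each cluster was not analysed here.

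Some transcripts stood out in single libraries. Control hippocampus DJ21 held 109 CPM of prolactin (Prl) and 41.7 CPM of growth hormone (Gh), both made in large amounts by the pituitary, while the other 15 libraries held at most 0.135 and 0.0895 CPM. Transthyretin (Ttr), the main transcript of the choroid plexus, was at 132 CPM in control cortex DJ6 and 202 CPM in knockout cortex DJ1, against 0.139 to 4.15 CPM in the other 6 cortices. Irs4 ranged from 0.499 to 13.7 CPM within hippocampus. Vgll3, which had the largest difference between the regions of all genes tested for it, ranged from 1.70 to 25.2 CPM among control hippocampi, the highest being DJ22.

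The immediate early gene Fos was highest in the libraries with the lowest numbers of each region. In cortex it was at 40.3 CPM in knockout DJ1, 24.1 in knockout DJ2 and 24.8 in control DJ3, and at 6.09 to 12.0 CPM in the others. In hippocampus it was at 19.8 CPM in knockout DJ15, 19.6 in knockout DJ16 and 10.4 in control DJ17, and at 3.58 to 5.32 CPM in the others. Fkbp5, which glucocorticoids induce, was at its lowest in the same libraries: 22.6, 26.7 and 22.8 CPM in cortex DJ1, DJ2 and DJ3, against 38.7 to 62.8 in the others, and 35.3, 47.8 and 43.6 CPM in hippocampus DJ15, DJ16 and DJ17, against 63.8 to 90.7 in the others. Both genotypes are among the libraries on each side.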
